A study of Homo sapiens with 12 samples.

How the data were processed

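MCF10A, a human mammary epithelial cell line that is not transformed, was compared in 3 groups: cells with a control vector (VEC) and cells stably expressing the intracellular domain (ICD) of the receptor tyrosine kinase ERBB4 in its CYT1 or its CYT2 form. RNA was labelled with biotin as cRNA by the Illumina TotalPrep kit, per the labels' protocols, and hybridised to 12 Illumina bead arrays. The array titles give each group 2 biological numbers, each with 2 technical numbers, so that 4 arrays stand for 2 biological replicates.

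Signals were deposited as average bead intensity per probe and array, neither background-subtracted nor normalised, per the file headers and the values. Beside each signal the authors deposited a detection p-value per probe and array, which moves in steps of 1 in 770, as a rank among negative control probes would. A second deposited table holds log2 values of the same arrays, named by sample, with no processing stated. Each of its columns equalled log2 of exactly 1 signal column over all probes, with a largest difference of 5e-09 against 0.829 to 1.27 for the next best column, so its scale is known, it is not centred, and it carries no ratio direction. The signals used are these sample-named values taken back to the linear scale. The names of the signal columns give the group, and their replicate is not clear from the names, so each array's detection p-values were joined to its sample through this identity of the values. Scanner software, its settings and any other software of the authors are not given in the sources used here.

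Signals were background-corrected with the negative controls inferred from the detection p-values, offset by 16, quantile-normalised and put on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3. A probe was kept when its detection p was under 0.05 on both technical arrays of at least 2 of the 6 biological replicates, which left 17356 probes. Technical arrays were averaged on the log2 scale and counted as 1 replicate. One limma model with the 3 groups was fitted to the 6 biological replicates, with 3 residual degrees of freedom and a prior of 3.07, and 3 contrasts were tested two-sided with moderated statistics. Benjamini-Hochberg adjustment was made within each contrast over all probes, and a probe with an adjusted p under 0.05 is called changed. Errors of log2 fold changes are the model's standard errors (SE), and fold changes are on the offset scale, which understates the change of dim probes. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

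The array annotation gave 1 gene symbol for 30113 probes, several for 8 and none in the table used here for 17202. Of the single symbols, 30074 were found in a human reference gene table, used for names only. Of the probes tested, 13455 carried a symbol, for 10371 genes. A gene is represented by its probe with the highest mean over all arrays, and a probe with several symbols or none is not named.

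Where a probe was not detected on any array of the dimmer group, only a bound is given. The bound sets the mean of the brighter group against the mean of, per array, the higher of the lowest signal among detected probes and the dim probe's own signal, all as normalised log2 values.

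The design, tests, alternatives, 33 gene lists and the rule for named genes were fixed before the data were examined. The lists hold 746 genes, of which 704 were on the array and 564 were tested. The lists for cholesterol synthesis, YAP/TEAD targets, NF-kB targets and cytokines, proteases and protease inhibitors were put in knowing that the study's publication discusses such genes, so they are not independent evidence. Lists were tested with limma's camera at its preset correlation of 0.01, two-sided, adjusted over the 33 lists, and again with an estimated correlation. The alternative fry tests ask whether a list's genes move on balance one way, or in either direction, and do not compare a list with other genes. Members called are counted after adjustment over all probes and, beside it, adjusted over the list alone.

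The named-gene rule took ERBB4, then per contrast the 8 largest rises and 8 largest falls among called genes whose 4 arrays in one group all lay on one side of the 4 arrays of the other. It then took up to 4 called members of each list with the largest change, filled to 2 with the members of smallest p, and for the 2 ICD effects 5 genes per direction called in both and those called in opposite directions. Other genes are said to be named after their values were seen.

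The model and the list test were tried on simulated data, with 200 of 17356 probes changed in each of 20 simulations per contrast. Averaged log2 values were drawn independently for each probe, so normalisation, filter, technical averaging and correlation between genes were not tested. Far more probes were called in the real contrasts against VEC, where the shares recovered may differ. For CYT1 against VEC, 1.8% of changes of 0.3 on the log2 scale, 45.7% of 0.6, 95.3% of 1 and 100% of 2 were recovered, with 5.87% false calls. For CYT2 against VEC the shares were 0.8%, 46.9%, 93.3% and 99.9%, with 5.84% false calls, and for CYT2 against CYT1 1.5%, 47.2%, 93.2% and 100%, with 4.98%. A list of 25 genes shifted by 0.3 was called in 100% of simulations in each contrast at the preset correlation. With an estimated correlation the same list was called in 5% for CYT1 against VEC, 0% for CYT2 against VEC and 5% for CYT2 against CYT1. That setting thus missed most true shifts of this size. As the genes were simulated without correlation, a call lost with an estimated correlation does not show that correlated genes produced it.

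Alternatives covered the background correction and scaling, the deposited log2 values, the detection filter, the biological number as a block, the technical arrays alone, as a block or with duplicateCorrelation, each pair of groups alone, another variance prior, other thresholds, other list tests and each biological replicate left out. Averaging the arrays that share a technical number was added after seeing the data, because these arrays were closer to each other than arrays titled technical replicates. Setting each ICD against its own VEC replicate was also added after seeing the data. The labels do not say how the replicates were separated, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Probe positions in the genome were not used here.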

Results

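ERBB4 is a member of the EGFR family of receptor tyrosine kinases, and its JM-a forms are cleaved so that a soluble ICD is released into the cell. The CYT1 form of the ICD holds a short stretch with a docking site for phosphoinositide 3-kinase that the CYT2 form lacks. Transcript levels were measured in MCF10A cells with control vector (VEC), with the CYT1 ICD and with the CYT2 ICD, all grown with serum. Each of the 3 groups had 4 arrays, taken as 2 biological replicates of 2 technical arrays. On an array 17514 to 18721 probes (37.0% to 39.6%) were above background. The medians of the deposited log2 values of the 12 arrays ran from 7.04 to 7.21.

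ERBB4 itself had 1 probe, which was above background on 0 of the 12 arrays, with detection p from 0.439 to 0.964 and raw signals of 102 to 127.2. Whether this probe lies within the part of the gene that encodes the ICD is not known here, so it checks neither the expression of the ICD nor the group labels, and no fold change is given.

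The first comparison asked which transcripts differ when the CYT1 ICD is present. The largest rises included DCN, which encodes the matrix proteoglycan decorin, at 5.07 ± 0.08 on the log2 scale (SE, n = 2 replicates per group), or 33.7-fold. FBXO32, a ubiquitin ligase subunit, rose by 4.55 ± 0.08 and CRYAB, a small heat shock protein, by 4.01 ± 0.14. TAGLN, an actin-binding protein of smooth muscle, rose by 3.72 ± 0.11 and the interferon-induced gene IFI44L by 3.63 ± 0.11. SRGN, ACKR1 and ANKRD1 were above background on 0 of the 4 VEC arrays and rose at least 38.6-fold, 20.4-fold and 12.2-fold. The largest falls were those of HS3ST1, a heparan sulfate sulfotransferase detected on 1 of 4 CYT1 arrays (-3.18 ± 0.14), of the serine protease PRSS3 (-2.91 ± 0.14), of the cornified envelope precursor SPRR2A (-2.80 ± 0.10) and of the chloride channel ANO1 (-2.68 ± 0.14). ERVMER34-1 (-2.33 ± 0.12) and TNFRSF6B, a soluble decoy receptor (-2.30 ± 0.09), followed. SPRR2E and NTSR1 were above background on 0 of the 4 CYT1 arrays and fell at least 5.28-fold and 3.26-fold. Probes of the SPRR2 and PRSS families, and of the MT1 family named further on, may not tell near-identical members apart.

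In all, 6229 of 17356 probes (35.9%) were called changed between CYT1 and VEC, 2895 higher and 3334 lower. These covered 1924 genes that rose and 2151 that fell, of which 532 and 192 changed at least 2-fold, and 1065 of the probes had no usable symbol. The balance depended on the scaling, with 3363 probes higher and 2922 lower under median scaling. Other probes of some named genes moved the same way but by other amounts: log2 fold changes ran from 0.46 to 3.63 for IFI44L, from 0.97 to 3.33 for COL8A1, from -1.76 to -0.71 for EGFR, from -1.51 to -0.83 for MUC1, from -0.95 to -0.49 for TAP2, from 0.94 to 1.46 for RARRES1 and from -2.13 to -1.52 for SOCS2.

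Mitosis (G2/M) genes showed the clearest common change of the 33 lists. Of 33 measured members 31 rose and 1 fell (31 and 1 adjusted over the list alone), with a median of 1.77 on the log2 scale. The median was 1.08 with quantile scaling of uncorrected signals and 0.99 with the deposited log2 values. Examples were KIF20A, a kinesin of the late mitotic spindle (3.13 ± 0.09), TOP2A, which untangles DNA before division (2.56 ± 0.15), and AURKB, a chromosomal passenger kinase (2.52 ± 0.10). The member that fell was the phosphatase CDC25B (-0.66), and BUB1B, at 0.24, did not pass; both were named after their values were seen. The list had a camera adjusted p of 9.5e-20, and an adjusted p = 0.0546 with an estimated correlation. Genes of DNA replication and G1/S did not move as a list (adjusted p = 0.646). Of 26 members 6 rose and 6 fell (6 and 7 adjusted over the list alone), among them TK1 (1.44 ± 0.09) and RRM2 (1.22 ± 0.10), which supply nucleotides, against the replicative helicase subunit MCM2 (-0.62 ± 0.09).

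Matrix and mesenchymal genes rose together. Of 22 extracellular matrix genes 15 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 1.27, or 0.99 with undetected members at their bounds (adjusted p = 2.7e-08). LOX, which cross-links collagen, rose by 3.42 ± 0.11, COL8A1 by 2.98 ± 0.09 and COL7A1 by 2.06 ± 0.08, while the laminin chain LAMB3 fell (-0.71, named after its value was seen). SPARC, a matrix glycoprotein detected on 2 of 4 VEC arrays, rose by 3.23 ± 0.09. Of 12 mesenchymal markers 9 rose and 1 fell (9 and 1 adjusted over the list alone, adjusted p = 0.000127), including TAGLN and CDH2, the gene of N-cadherin (1.54 ± 0.09), against the transcription factor FOXC2 (-0.66, named after its value was seen). Of 15 fibroblast markers on the array 8 passed the detection filter, some of them only through ICD arrays. Of these 8, 7 rose and 0 fell by limma, the same adjusted over the list alone (adjusted p = 5.5e-05). They were led by DCN and FAP, a membrane protease of activated fibroblasts (3.15 ± 0.09), while COL1A2, the exception, stood at -0.24 and did not pass. TGF-beta targets also rose as a list (12 of 20 rose and 3 fell, the same adjusted over the list alone, adjusted p = 0.00165), with CCN2, a matricellular protein, at 3.21 ± 0.08 and TGFB2 at 2.17 ± 0.17. With an estimated correlation the adjusted p = 0.0838 for the matrix, mesenchymal and fibroblast lists, and adjusted p = 0.103 for the TGF-beta list.

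Among 20 genes of epithelial adhesion and tight junctions 14 fell and 1 rose (16 and 1 adjusted over the list alone), with a median of -0.58, or -0.49 with undetected members at their bounds (adjusted p = 0.000127; adjusted p = 0.0838 with an estimated correlation). The membrane protease ST14 fell (-1.07 ± 0.11), as did CLDN7, a claudin (-0.93 ± 0.08), and MARVELD3, a tight junction protein above background on 0 of the 4 CYT1 arrays (at least 1.78-fold lower), whereas the desmosomal gene DSP rose (0.47, named after its value was seen). ERK-response genes fell as a list, 12 of 25 with 3 rising (16 and 4 adjusted over the list alone, adjusted p = 0.00897; adjusted p = 0.128 with an estimated correlation). SPRY2 (-1.44 ± 0.09) and DUSP4 (-1.29 ± 0.14), both feedback inhibitors of ERK signalling, and the AP-1 gene FOSL1 (-1.37 ± 0.10) were among them. The genes that rose were EPHA4 (0.76), JUNB (0.74) and ETV5 (0.64), named after their values were seen.

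Genes of cholesterol synthesis rose almost throughout: 17 of 19 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.78 (adjusted p = 4.5e-08; adjusted p = 0.0838 with an estimated correlation). ACAT2, which makes the acetoacetyl-CoA used by the pathway, rose by 1.995 ± 0.09 and DHCR7, its last reductase, by 1.65 ± 0.11. MVD, which makes isopentenyl diphosphate, rose by 1.54 ± 0.10, and PMVK fell (-0.54, named after its value was seen). Fatty acid and triglyceride synthesis rose as a list, with 7 of 14 genes higher and 2 lower (8 and 3 adjusted over the list alone, adjusted p = 0.0105; adjusted p = 0.141 with an estimated correlation). The desaturase SCD rose by 1.44 ± 0.08 and GPAM, the first enzyme of glycerolipid synthesis, by 1.46 ± 0.11, while the elongase ELOVL6 (-0.82) and ACACA (-0.40), named after their values were seen, fell. YAP/TEAD targets rose too: 16 of 25 rose and 3 fell (16 and 4 adjusted over the list alone, median 0.71, adjusted p = 2.4e-05; adjusted p = 0.0838 with an estimated correlation). CCN1 rose by 2.63 ± 0.08 beside ANKRD1 and CCN2, and FJX1 (-0.78), NT5E (-0.68) and F3 (-0.59), named after their values were seen, fell. As the cholesterol and YAP/TEAD lists were chosen with the study's publication in mind, their calls are not independent evidence.

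Of 30 interferon-stimulated genes 18 rose and 5 fell (19 and 5 adjusted over the list alone), with a median of 0.58 (adjusted p = 3.1e-05; adjusted p = 0.0838 with an estimated correlation). IFITM1, above background on 0 of the 4 VEC arrays, rose at least 6.47-fold, MX1, detected on 3 of them, by 2.68 ± 0.12 and IFI27 by 2.21 ± 0.12. The members that fell, named after their values were seen, were ISG20 (-1.15), USP18 (-0.49), OAS3 (-0.44), DDX60 (-0.42) and IFI35 (-0.37). Of 25 hypoxia and glycolysis genes 15 rose and 1 fell (17 and 2 adjusted over the list alone), including PFKFB4, a regulator of glycolytic flux (2.51 ± 0.10), and BNIP3L, which acts in mitophagy (2.16 ± 0.10), while the hexokinase HK2 fell (-0.51, named after its value was seen; list adjusted p = 1.1e-05). In the p53 list 12 of 21 rose and 1 fell (14 and 2 adjusted over the list alone, adjusted p = 0.000362), with TP53INP1 at 1.46 ± 0.11 and RRM2B at 1.03 ± 0.08, against SERPINB5 (-0.44, named after its value was seen). For these hypoxia and p53 lists the adjusted p = 0.0838 with an estimated correlation. NRF2 antioxidant genes rose in 7 of 16 cases and fell in 0 by limma, the same adjusted over the list alone (adjusted p = 0.0146; adjusted p = 0.296 with an estimated correlation), with TXNRD1, a thioredoxin reductase, at 1.62 ± 0.08. The NRF2 call ended with technical arrays 1 alone (adjusted p = 0.0517).

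The other 18 lists were not called as a whole, though single members changed. Among ERBB receptors and ligands EGFR (-1.76 ± 0.08) and the EGFR ligand TGFA (-1.41 ± 0.15) fell and the EGFR inhibitor ERRFI1 rose (0.62 ± 0.10), with 2 of 8 genes rising and 3 falling (2 and 4 adjusted over the list alone, adjusted p = 0.646). NF-kB targets and cytokines split into 6 rises and 9 falls among 27 (the same adjusted over the list alone, adjusted p = 0.619), with complement factor CFB at 1.70 ± 0.10 and lipocalin LCN2 at -1.65 ± 0.10. Proteases split into 9 rises and 7 falls among 22 (10 and 7 adjusted over the list alone, adjusted p = 0.685), with KLK5 (2.13 ± 0.10) and MMP9 (1.77 ± 0.08) against PRSS3. Protease inhibitors split into 6 and 6 among 18 (7 and 6 adjusted over the list alone, adjusted p = 0.704), with SERPINA3 at 1.75 ± 0.10. Of 14 basal markers 6 rose and 4 fell (the same adjusted over the list alone, adjusted p = 0.704), with KRT14 (1.60 ± 0.09) against the integrin ITGA6 (-1.84 ± 0.16). Luminal markers had 1 rise and 3 falls among 11 (2 and 5 adjusted over the list alone, adjusted p = 0.118), including ALDH1A3 (-1.28 ± 0.08) and MUC1 (-0.83 ± 0.09). Of 9 milk protein and STAT5 targets 4 fell and 0 rose by limma (5 and 0 adjusted over the list alone, adjusted p = 0.167), SOCS2, a cytokine signalling inhibitor, by the most (-1.52 ± 0.08).

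Cornified envelope genes had 4 rises and 4 falls among 17 (4 and 5 adjusted over the list alone, adjusted p = 0.944), with SPRR1B (-1.70 ± 0.09) and SPRR2A against SBSN (1.49 ± 0.09). The unfolded protein response and ATF4 list had 6 rises and 10 falls among 26 (8 and 12 adjusted over the list alone, adjusted p = 0.864), with ATF3 (1.28 ± 0.08) and PHGDH, of serine synthesis (1.25 ± 0.09), against the chaperone DNAJC3 (-0.70 ± 0.10). In antigen presentation 4 of 12 fell and 0 rose by limma (4 and 2 adjusted over the list alone, adjusted p = 0.542), TAP2 among them (-0.95 ± 0.11). Metallothioneins and zinc genes had 4 rises and 1 fall among 6 (the same adjusted over the list alone, adjusted p = 0.0659), with MT1X at 1.01 ± 0.08 and MT1F at -0.63 ± 0.09. The list was called up with quantile scaling of uncorrected signals (adjusted p = 0.0282) and with the deposited log2 values (adjusted p = 0.0121), and without VEC replicate 1 (adjusted p = 0.0418). Notch genes had 4 rises and 1 fall among 9 (the same adjusted over the list alone, adjusted p = 0.383), and estrogen response genes 5 and 1 among 12 (5 and 3 adjusted over the list alone, adjusted p = 0.259). The latter were called up with the deposited log2 values (adjusted p = 0.0215) at a median of -0.003. Oxidative phosphorylation had 2 rises and 3 falls among 37 (1 and 3 adjusted over the list alone, adjusted p = 0.646). Ribosomal proteins had 5 and 2 among 42 (3 and 0 adjusted over the list alone, adjusted p = 0.816). With median scaling that list had a median of 0.15 and was called up (adjusted p = 0.0282). Of the markers of other cell types, 1 of 2 endothelial genes fell (1 adjusted over the list alone, adjusted p = 0.331), 2 of 6 leukocyte genes rose and 2 fell (the same adjusted over the list alone, adjusted p = 0.864), and 2 of 10 luminal breast cancer line genes rose and 1 fell (3 and 3 adjusted over the list alone, adjusted p = 0.864).

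Median, mean and test direction differed in sign for 7 of these lists. The medians and means were 0.05 and -0.02 for proteases, -0.15 and 0.18 for protease inhibitors, -0.07 and 0.11 for basal markers, -0.16 and 0.01 for the unfolded protein response, -0.01 and 0.03 for ribosomal proteins, -0.003 and 0.35 for leukocyte markers and -0.09 and 0.11 for luminal cancer line markers. With median scaling the last 2 medians were 0.07 and 0.04. Medians of called lists were as small as 0.60 for matrix genes, 0.46 for YAP/TEAD targets and 0.36 for interferon-stimulated genes with the deposited log2 values, and -0.29 for epithelial adhesion with no detection filter, all still called. The deposited values also gave 0.11 for NRF2 genes, 0.21 for TGF-beta targets, 0.21 for the p53 list and 0.22 for fatty acid synthesis. Without a detection filter further list members come in, so the medians are over more genes. The median of fibroblast markers then went from 1.43 to 0.36 and that of mesenchymal markers from 1.05 to 0.48. These lists too stayed called. Without VEC replicate 1 or 2 the count of changed probes was 3969 or 3994, and 22 of the 133 called genes of the naming rule lost their call when 1 replicate or another was left out.

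**Figure D1:**
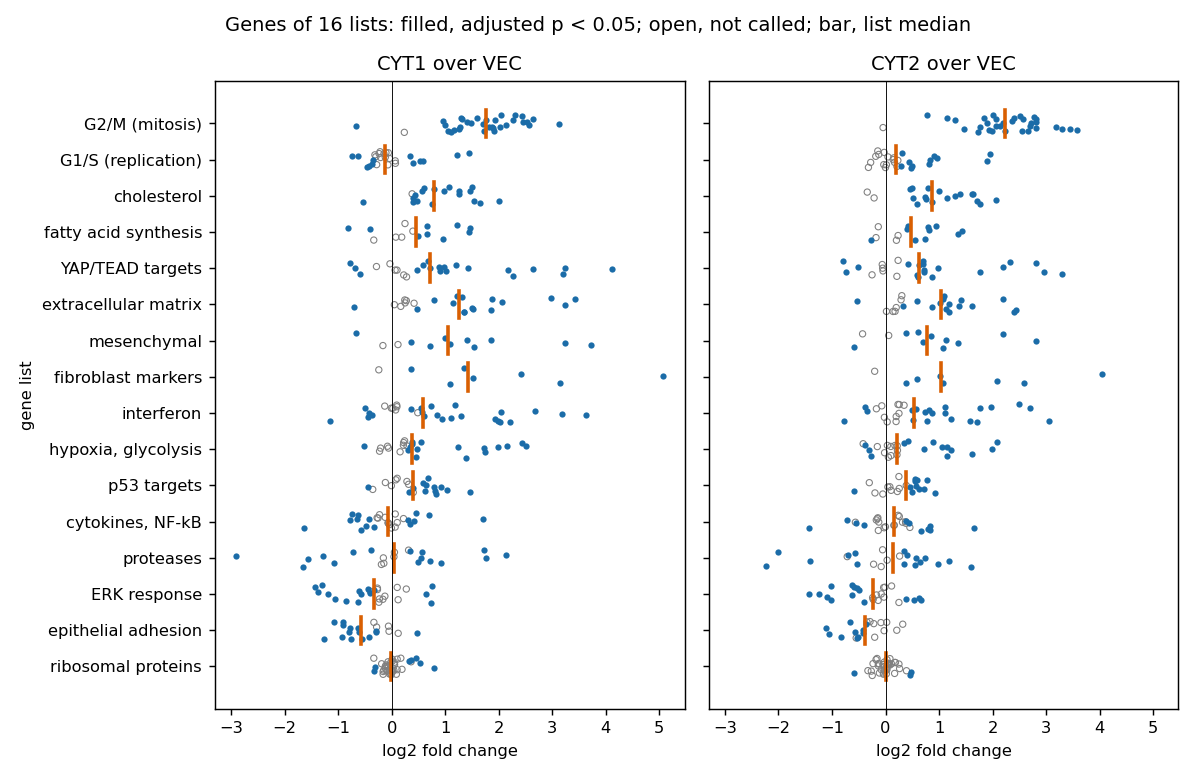
Log2 fold changes of the measured members of 16 gene lists in CYT1 against VEC and CYT2 against VEC, 1 point per gene, with filled points for adjusted p under 0.05, open points for genes that were not called and a bar at the list median. Mitosis (G2/M) genes lie at a median of 1.77 for CYT1 and 2.23 for CYT2, and epithelial adhesion genes at -0.58 and -0.39.

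The second comparison asked the same of the CYT2 ICD. DCN again rose by 4.05 ± 0.08 on the log2 scale (SE, n = 2), or 16.5-fold, and FBXO32 by 3.95 ± 0.08. SRGN, ACKR1 and ANKRD1, undetected on all 4 VEC arrays, rose at least 28.1-fold, 12.4-fold and 6.94-fold. Mitosis genes were among the largest rises here, with KIF20A at 3.57 ± 0.09, AURKB at 3.45 ± 0.10 and CDCA3, undetected in VEC, at least 6.33-fold higher. The largest falls were those of HS3ST1 (-2.56 ± 0.14, detected on 3 of 4 CYT2 arrays), ERVMER34-1 (-2.23 ± 0.12), PRSS3 (-2.23 ± 0.14) and SPRR2E (-2.18 ± 0.17, detected on 3 of 4). Next came the cell surface protein FLRT3 (-2.17 ± 0.09), TNFRSF6B (-2.16 ± 0.09), NTSR1 (-2.03 ± 0.14, detected on 1 of 4) and SPRR2A (-2.02 ± 0.10). Called probes numbered 5272 (30.4%), 2558 higher and 2714 lower, for 1665 genes that rose and 1822 that fell, 440 and 120 of them at least 2-fold. Of the probes 862 had no usable symbol. Under median scaling 2932 probes were higher and 2415 lower. Between probes of a gene the log2 fold changes ran from 0.57 to 3.05 for IFI44L, from 1.08 to 2.82 for BIRC5, from 0.79 to 2.53 for COL8A1, from 1.14 to 2.04 for FN1, from -2.18 to -1.44 for SPRR2E and from -1.25 to -0.44 for EGFR.

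Of 33 mitosis genes 32 rose and 0 fell by limma, the same adjusted over the list alone, with a median of 2.23 (1.47 with the deposited log2 values; adjusted p = 7.4e-27), and the call held with an estimated correlation (adjusted p = 0.0346). Among them were DLGAP5, a spindle protein detected on 2 of 4 VEC arrays (3.30 ± 0.09), and TOP2A (3.18 ± 0.15); CDC25B, named after its value was seen, stood at -0.05 and did not pass. G1/S genes were called up here, with 11 of 26 rising and 0 falling by limma (11 and 1 adjusted over the list alone), a median of 0.19 and adjusted p = 0.00189 (adjusted p = 0.138 with an estimated correlation). TK1 rose by 1.95 ± 0.09, RRM2 by 1.90 ± 0.10, the transcription factor E2F2 by 0.97 ± 0.11 and the replication initiation gene CDC45 by 0.90 ± 0.10.

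Matrix genes rose in 15 of 22 cases and fell in 1 (the same adjusted over the list alone), with a median of 1.04, or 0.94 with undetected members at their bounds (adjusted p = 4.8e-08; adjusted p = 0.104 with an estimated correlation). COL8A1 rose by 2.43 ± 0.09, LOX by 2.41 ± 0.11 and SPARC by 2.20 ± 0.09, against LAMB3 (-0.53, named after its value was seen). Mesenchymal markers had 9 rises and 1 fall among 12 (9 and 2 adjusted over the list alone, adjusted p = 0.000621), with TAGLN at 2.81 ± 0.11 and CDH2 at 1.36 ± 0.09 against the EMT factor SNAI2 (-0.60, named after its value was seen). FN1, detected on 2 of 4 VEC arrays, rose as well (1.14 ± 0.20), but without CYT2 replicate 2 its call was lost (adjusted p = 0.0506). The 8 of 15 fibroblast markers that passed the detection filter had 7 rises and 0 falls by limma, the same adjusted over the list alone (adjusted p = 8.8e-05). DCN and FAP (2.59 ± 0.09) were among the rises, and COL1A2 stood at -0.20 and did not pass. TGF-beta targets had 9 rises and 1 fall among 20 (10 and 1 adjusted over the list alone, adjusted p = 0.0078), with CCN2 at 2.96 ± 0.08 and TGFB2 at 1.76 ± 0.17 against the inhibitor TIMP3 (-0.55, named after its value was seen). With an estimated correlation these gave adjusted p = 0.114 for the mesenchymal and fibroblast lists and adjusted p = 0.138 for the TGF-beta list.

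Epithelial adhesion genes fell in 10 of 20 cases and rose in 0 by limma (14 and 1 adjusted over the list alone, median -0.39, adjusted p = 0.00156; adjusted p = 0.114 with an estimated correlation). The desmosomal gene PKP3 fell (-1.11 ± 0.09), and MARVELD3 and MARVELD2, undetected on all 4 CYT2 arrays, fell at least 1.79-fold and 1.33-fold. ERK-response genes had 11 falls and 4 rises among 25 (the same adjusted over the list alone, adjusted p = 0.0423; adjusted p = 0.181 with an estimated correlation), SPRY2 (-1.44 ± 0.09) and TRIB1 (-1.25 ± 0.08) among the falls. LIF (0.66), ETV5 (0.63), EPHA4 (0.54) and JUNB (0.39), named after their values were seen, rose. Milk protein and STAT5 targets had 5 falls and 0 rises by limma among 9, the same adjusted over the list alone (adjusted p = 0.0423; adjusted p = 0.201 with an estimated correlation). SOCS2 fell (-1.58 ± 0.08), as did PIM1 (-0.68 ± 0.09) and CISH, undetected on all 4 CYT2 arrays (at least 1.20-fold lower), all targets of STAT5. The STAT5 call ended with median scaling (adjusted p = 0.0538), with the biological block (0.0597), without a detection filter (0.0600) or with the strict one (0.0865), with technical arrays 2 alone (0.0680) and without VEC replicate 2 (0.0566). The ERK-response call ended with the block (adjusted p = 0.0600), without VEC replicate 2 (0.0517) and without either CYT1 replicate (0.0553).

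For cholesterol synthesis 17 of 19 genes rose and 0 fell by limma, the same adjusted over the list alone, with a median of 0.87 (adjusted p = 1.2e-08; adjusted p = 0.104 with an estimated correlation). ACAT2 rose by 2.07 ± 0.09, DHCR7 by 1.77 ± 0.11 and HMGCS1, which makes HMG-CoA, by 1.63 ± 0.11. Fatty acid synthesis had 9 rises and 1 fall among 14 (the same adjusted over the list alone, adjusted p = 0.000702; adjusted p = 0.114 with an estimated correlation), with SCD (1.42 ± 0.08) and the desaturase FADS1 (1.36 ± 0.08) against ELOVL6 (-0.27, named after its value was seen). YAP/TEAD targets had 16 rises and 3 falls among 25 (16 and 4 adjusted over the list alone, median 0.63, adjusted p = 5.5e-05; adjusted p = 0.104 with an estimated correlation). They included CCN1 (2.33 ± 0.08) and BIRC5 (2.82 ± 0.12), which is also a mitosis gene, against F3 (-0.79), FJX1 (-0.74) and NT5E (-0.52), named after their values were seen. The cholesterol and YAP/TEAD lists carry the same caveat on independence as for CYT1.

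Interferon-stimulated genes had 17 rises and 3 falls among 30 (the same adjusted over the list alone, median 0.54, or 0.51 with undetected members at their bounds, adjusted p = 1.6e-06; adjusted p = 0.104 with an estimated correlation), with IFI44L at 3.05 ± 0.11, IFITM1 at least 4.65-fold higher and IFI27 at 1.96 ± 0.12. ISG20 (-0.77), DDX60 (-0.38) and USP18 (-0.35), named after their values were seen, fell. Hypoxia and glycolysis genes had 11 rises and 3 falls among 25 (11 and 4 adjusted over the list alone, adjusted p = 0.000702; adjusted p = 0.138 with an estimated correlation), with PFKFB4 at 1.99 ± 0.10. NDRG1 (-0.39), SLC2A1 (-0.31) and PFKP (-0.28), named after their values were seen, fell. The p53 list had 10 rises and 1 fall among 21 (the same adjusted over the list alone, adjusted p = 0.00189; adjusted p = 0.114 with an estimated correlation), with TP53INP1 at 0.92 ± 0.11 against SERPINB5 (-0.59, named after its value was seen). NRF2 genes had 7 rises and 0 falls by limma among 16 (8 and 0 adjusted over the list alone, adjusted p = 0.00156; adjusted p = 0.175 with an estimated correlation), with TXNRD1 at 1.44 ± 0.08. Metallothioneins had 4 rises and 0 falls by limma among 6, the same adjusted over the list alone (adjusted p = 0.0152; adjusted p = 0.289 with an estimated correlation), with MT1X at 1.03 ± 0.08.

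The remaining 16 lists were not called. EGFR (-1.25 ± 0.08) and TGFA (-1.33 ± 0.15) fell among 8 ERBB receptors and ligands, with 1 rise and 3 falls (the same adjusted over the list alone, adjusted p = 0.76). NF-kB targets had 7 rises and 4 falls among 27 (8 and 5 adjusted over the list alone, adjusted p = 0.26), with CFB (1.64 ± 0.10) and the mitochondrial dismutase SOD2 (0.83 ± 0.08) against LCN2 (-1.44 ± 0.10). Proteases had 10 rises and 6 falls among 22 (10 and 8 adjusted over the list alone, adjusted p = 0.491), with PRSS23 (1.60 ± 0.11) against MMP7 (-2.01 ± 0.08) and MMP1, undetected on all 4 CYT2 arrays (at least 2.28-fold lower). Protease inhibitors had 6 and 6 among 18, the same adjusted over the list alone (adjusted p = 0.915), with SERPINA3 at 2.12 ± 0.10. Basal markers had 4 rises and 5 falls among 14, the same adjusted over the list alone (adjusted p = 0.959), with KRT5 (0.95 ± 0.08) against ITGA6 (-1.70 ± 0.16). Luminal markers had 3 and 4 among 11 (3 and 5 adjusted over the list alone, adjusted p = 0.811), with KRT8 at 1.01 ± 0.12. Cornified envelope genes had 4 and 5 among 17 (4 and 7 adjusted over the list alone, adjusted p = 0.603), with KRT80 (1.41 ± 0.08) against SPRR3 (-1.26 ± 0.15).

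The unfolded protein response list had 6 rises and 10 falls among 26 (6 and 12 adjusted over the list alone, adjusted p = 0.959). Antigen presentation had 0 rises by limma and 5 falls among 12 (the same adjusted over the list alone, adjusted p = 0.0939). That list was called down with no detection filter (adjusted p = 0.0238), without VEC replicate 2 (0.0491) and without CYT2 replicate 2 (0.04998). Notch had 2 and 1 among 9 (3 and 1 adjusted over the list alone, adjusted p = 0.614), where the ligand JAG1 fell (-0.87 ± 0.08). Estrogen response genes had 5 and 4 among 12, the same adjusted over the list alone (adjusted p = 0.367), with the carbonic anhydrase CA12 at 1.16 ± 0.10. Oxidative phosphorylation had 1 and 3 among 37 (0 and 0 adjusted over the list alone by limma, adjusted p = 0.959) and ribosomal proteins 2 and 1 among 42 (0 and 0 adjusted over the list alone by limma, adjusted p = 0.844). Neither of 2 endothelial markers passed, with ENG at -0.21 and ROBO4 at -0.19 (adjusted p = 0.526 for the list). Leukocyte markers had 3 rises and 1 fall among 6 (the same adjusted over the list alone, adjusted p = 0.603) and luminal cancer line markers 3 and 2 among 10 (the same adjusted over the list alone, adjusted p = 0.204). Signs of median, mean and test differed for proteases (median 0.15, mean -0.04), protease inhibitors (-0.165 and 0.135), ERBB genes (0.02 and -0.22), the unfolded protein response (-0.10 and 0.02) and Notch (-0.02 and 0.03). With median scaling the Notch median was 0.06, and with the deposited log2 values the ERBB median was -0.10. Of the called lists, medians were as small as 0.06 for G1/S genes and 0.40 for YAP/TEAD targets with the deposited log2 values, 0.33 for matrix genes and -0.22 for epithelial adhesion with no detection filter, and 0.25 for interferon-stimulated genes with the strict one, all still called. The deposited values also gave 0.08 for hypoxia and glycolysis, 0.13 for NRF2 genes, 0.13 for TGF-beta targets and 0.17 for the p53 list. Without a detection filter further list members come in, and the strict one leaves members out, so these medians are over other genes. Without a filter the median of fibroblast markers went from 1.04 to 0.24 and that of mesenchymal markers from 0.77 to 0.32. These lists too stayed called.

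Leaving out single replicates lowered the CYT2 count: 3020 and 3033 probes were called without VEC replicate 1 or 2, and 3094 and 3185 without CYT2 replicate 1 or 2. Of the 131 called genes of the naming rule 23 lost their call without some replicate.

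Set side by side, the differences of the CYT1 and CYT2 groups from VEC went largely in the same direction. Called in both comparisons were 2143 probes as higher (1424 genes) and 2167 as lower (1477 genes), where independent lists would share 426.7 and 521.3. Besides SRGN, DCN, ACKR1, FBXO32 and ANKRD1, which rose in both, HS3ST1, PRSS3, SPRR2E, ERVMER34-1 and TNFRSF6B fell in both. Opposite calls were made for 5 probes and 2 genes. RARRES1, a retinoid-responsive gene, rose with CYT1 (1.46 ± 0.13) and fell with CYT2 (-0.72 ± 0.13), and SLCO2A1, a prostaglandin transporter, fell with CYT1 (-0.31 ± 0.09) and rose with CYT2 (0.74 ± 0.09). The fall of RARRES1 lost its call without VEC replicate 2 (adjusted p = 0.0513), and that of SLCO2A1 without any single replicate (adjusted p = 0.0594 to 0.164).

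Across probes, which are not independent replicates, the fold changes correlated with r = 0.906 and shared their sign in 83.8% of cases. Both comparisons use the same VEC arrays, and 100 simulations of unchanged groups against shared controls gave r = 0.5003, 66.7% equal signs and 0 probes called in both by limma. Shared controls and independent noise per probe fix such values in advance. Errors common to many probes of an array were not simulated, so the simulations do not test the overlap. The covariance was 0.245 against 0.00902 simulated, a difference of 0.236. With separate controls, chosen after seeing the data, CYT1 set against VEC replicate 1 and CYT2 against VEC replicate 2 shared 1395 probes as higher and 926 as lower (207 and 142.9 for independent lists), with r = 0.826 and a covariance of 0.233. The other assignment gave 1398 and 920 probes. Each control was then 1 replicate, and a state common to both VEC replicates stays shared, so part of the excess overlap may still come from the controls.

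**Figure D2:**
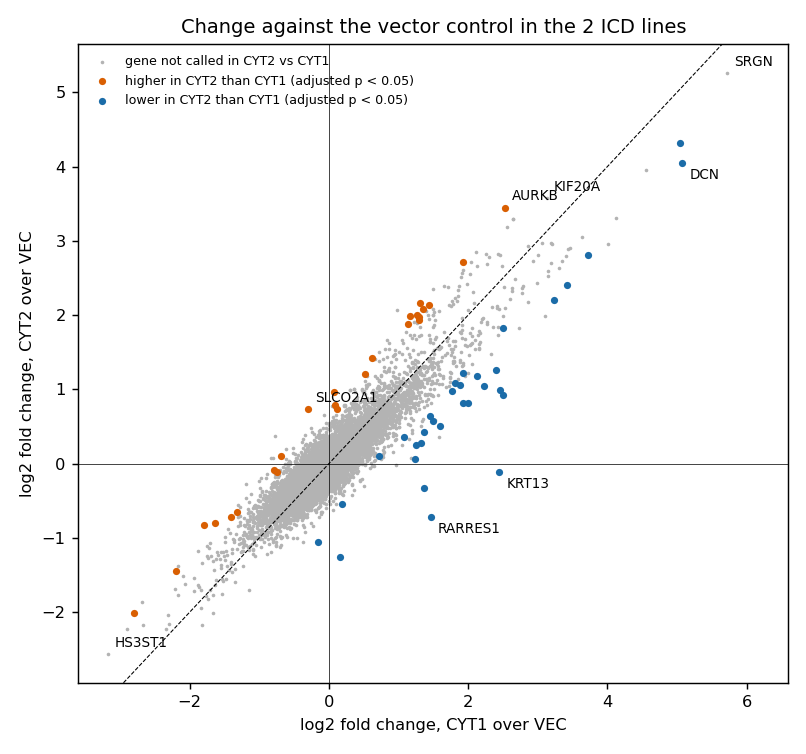
Log2 fold change of CYT1 over VEC (horizontal axis) against that of CYT2 over VEC (vertical axis), 1 point per gene, with genes higher in CYT2 than in CYT1 in orange and genes lower in CYT2 in blue. Most genes lie near the diagonal, and RARRES1 lies at 1.46 and -0.72.

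The direct comparison of the ICD groups called few genes. The level of the ICDs was not measured here, and the labels do not say how the replicates were separated. Whether a difference comes from the ICD form, its level or the cell populations was not tested and cannot be told apart here. KRT13, a keratin of stratified epithelia, was above background on 0 of the 4 CYT2 arrays and was at least 4.84-fold lower in CYT2 than in CYT1 (adjusted p = 0.0055). RARRES1 was lower by -2.18 ± 0.13 on the log2 scale (SE, n = 2, adjusted p = 0.0211). It was followed by SERPINB13 (-1.70 ± 0.12, detected on 3 of 4 CYT2 arrays), the actin-bundling gene LCP1 (-1.57 ± 0.17), IGFBP4 (-1.47 ± 0.14, detected on 3 of 4), SPRR3 (-1.42 ± 0.15), IGFBP7 (-1.18 ± 0.09) and FBLN5 (-1.18 ± 0.11, detected on 2 of 4). Higher in CYT2 were SLCO2A1 (1.04 ± 0.09, adjusted p = 0.0305), AURKB (0.92 ± 0.10), E2F2 (0.90 ± 0.11), FAM83D (0.85 ± 0.10), ADAM8 (0.84 ± 0.10), MXD3 (0.82 ± 0.10) and STMN1 (0.81 ± 0.08). MAD1L1 was higher on 1 probe (0.96 ± 0.08) and not on another (-0.04), and the 3 probes of STMN1 ran from 0.22 to 0.81. Called probes numbered 82, 35 higher and 47 lower in CYT2, for 25 and 32 genes, of which 1 and 17 differed at least 2-fold. Of the probes 12 had no usable symbol. In the same limma fit 3029 of 17356 probes had an unadjusted p under 0.05. In the simulations 1.5% of changes of 0.3 were recovered, so the low count of calls does not show that the groups are alike.

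Every one of the 32 called genes of the naming rule lost its call when some replicate was left out, and the count then fell to 0 to 3 probes. Averaging arrays by technical number instead, chosen after seeing the data, gave 23 probes, 17 of them among the 82, and with the biological number as a block 2 probes were called. Other settings called more, with most of them higher in CYT2: 1094 with duplicateCorrelation (620 higher and 474 lower), 994 with quantile scaling of uncorrected signals (545 and 449), 706 with the deposited log2 values (434 and 272) and 514 with the strict detection filter (324 and 190). The technical number as a block gave 932 (539 and 393) and a trended robust prior 1096 (622 and 474). In the duplicateCorrelation fit the consensus correlation of arrays titled technical replicates was -0.1442, and a negative value lowers the errors of group means. For arrays that share a technical number it was 0.07387.

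Mitosis genes were the list with the clearest difference. Of 33 members 4 were higher in CYT2 and 0 lower by limma (32 and 0 adjusted over the list alone), with a median difference of 0.55 and adjusted p = 5.4e-26, and the call held with an estimated correlation (adjusted p = 0.0363). The 4 were AURKB, UBE2C (0.78 ± 0.10), CDCA8 (0.73 ± 0.09) and AURKA (0.64 ± 0.08). G1/S genes were also higher as a list, 1 of 26 by single tests (19 and 0 adjusted over the list alone), with a median of 0.35 (adjusted p = 1.3e-14; adjusted p = 0.0869 with an estimated correlation). NF-kB targets and cytokines had a median of 0.21 with 0 of 27 called by limma (10 and 0 adjusted over the list alone, adjusted p = 8.1e-05). Luminal markers had a median of 0.22 with 0 of 11 called by limma (4 and 0 adjusted over the list alone, adjusted p = 0.00294) and epithelial adhesion 0.14 (0.11 with undetected members at their bounds) with 1 of 20 called (3 and 1 adjusted over the list alone, adjusted p = 0.0223), the adhesion gene EPCAM (0.71 ± 0.08; 0.69 to 1.12 over its 3 probes). With an estimated correlation these 3 lists had adjusted p = 0.152, 0.152 and 0.174.

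Lower in CYT2 as lists were matrix genes (median -0.14, 2 of 22 called, 6 adjusted over the list alone, adjusted p = 0.000704) and mesenchymal markers (-0.29, 2 of 12 called, 5 adjusted over the list alone, adjusted p = 0.00079). So were fibroblast markers (-0.42, 1 of 8 called, 3 adjusted over the list alone, adjusted p = 0.00299). The members called were SPARC (-1.03 ± 0.09), LOX (-1.01 ± 0.11), TAGLN (-0.91 ± 0.11) and DCN (-1.03 ± 0.08). YAP/TEAD targets (-0.16, 1 of 25 called, 5 lower and 1 higher adjusted over the list alone, adjusted p = 0.00337) and estrogen response genes (-0.15, 1 of 12 called, 3 adjusted over the list alone, adjusted p = 0.00932) followed, with SPARC and IGFBP4 as their called members. Hypoxia and glycolysis (-0.14, 8 of 25 adjusted over the list alone, adjusted p = 6.1e-06), TGF-beta targets (-0.17, 1 of 20 adjusted over the list alone, adjusted p = 0.028) and the p53 list (-0.11, 0 of 21 adjusted over the list alone by limma, adjusted p = 0.00883) were lower with no member called over all probes by limma. With an estimated correlation the adjusted p = 0.152 for the matrix, mesenchymal, fibroblast, YAP/TEAD, hypoxia and p53 lists, adjusted p = 0.158 for the estrogen list and adjusted p = 0.184 for the TGF-beta list. The strict detection filter ended the calls of 4 lists: epithelial adhesion (adjusted p = 0.0541), TGF-beta (0.0594), YAP/TEAD (0.0656) and estrogen response (0.0725). Without CYT1 replicate 2 those of epithelial adhesion, TGF-beta and estrogen response ended too. With technical arrays 1 alone the matrix list (0.177) and TGF-beta list (0.107) were not called, nor was epithelial adhesion with technical arrays 2 alone (0.144). The TGF-beta call also ended with no detection filter (0.0524) and without CYT2 replicate 1 (0.163). Medians were as small as 0.14 for NF-kB targets with quantile scaling of uncorrected signals, and -0.10 for YAP/TEAD and -0.09 for TGF-beta targets with the deposited log2 values. With no detection filter, which lets in further list members, the medians were 0.12 for luminal, 0.08 for epithelial adhesion, -0.12 for mesenchymal and -0.04 for fibroblast markers. The matrix median was -0.07 with technical arrays 1 alone, -0.36 with technical arrays 2 alone and -0.24 without CYT2 replicate 1, and that of YAP/TEAD targets -0.10 without CYT1 replicate 2.

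The other 20 lists were not called. Basal markers came nearest (adjusted p = 0.054), with ACTG2, detected on 2 of 4 CYT2 arrays (-1.10 ± 0.09), and KRT14 (-1.09 ± 0.09) lower and 2 of 14 called (3 lower and 1 higher adjusted over the list alone). The list was called down with quantile scaling of uncorrected signals (adjusted p = 0.0325), median scaling (adjusted p = 0.0373), the deposited log2 values (adjusted p = 0.00293), no detection filter (adjusted p = 0.0109) and duplicateCorrelation (adjusted p = 0.0444). Cornified envelope genes had SPRR2A higher (0.78 ± 0.10) and KRT13, SPRR3 and SBSN (-0.92 ± 0.09) lower among 17 (5 and 3 adjusted over the list alone, adjusted p = 0.588). Proteases had KLK5 (-0.95 ± 0.10) and MMP9 (-0.79 ± 0.08) lower among 22 (4 higher and 3 lower adjusted over the list alone, adjusted p = 0.863). Protease inhibitors had SERPINB13 lower among 18 (1 adjusted over the list alone, adjusted p = 0.717). Of 30 interferon-stimulated genes OAS2 was lower (-0.71 ± 0.08; 2 higher and 6 lower adjusted over the list alone, adjusted p = 0.146). Of 6 leukocyte markers CD14 was higher (0.64 ± 0.08) and LCP1 lower (2 and 2 adjusted over the list alone, adjusted p = 0.828).

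In the remaining 14 lists 0 members were called by limma over all probes. Their adjusted p were 0.127 for cholesterol synthesis (1 of 19 lower adjusted over the list alone; called up with the strict detection filter at 0.0380), 0.22 for fatty acids (1 of 14 higher and 1 lower), 0.282 for ERK-response genes (1 of 25 higher) and 0.511 for ERBB genes (1 of 8 higher). They were 0.828 for the unfolded protein response (1 of 26 lower), 0.276 for metallothioneins (1 of 6 higher), 0.37 for endothelial markers (1 of 2 higher) and 0.282 for luminal cancer line markers (3 of 10 higher and 1 lower). Adjusted over the list alone, 0 members passed by limma in the other 6, with adjusted p of 0.448 for STAT5 targets, 0.434 for antigen presentation, 0.282 for Notch, 0.581 for NRF2, 0.282 for oxidative phosphorylation and 0.828 for ribosomal proteins. EGFR, at 0.51 ± 0.08 (0.27 on its other probe), did not pass (adjusted p = 0.0666), nor did IL24, at 1.15 ± 0.17 (adjusted p = 0.0593).

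Median, mean and test differed in sign for proteases (median 0.01, mean -0.02), protease inhibitors (0.07 and -0.05), ERK-response genes (-0.0009 and 0.07), the unfolded protein response (-0.01 and 0.01), cornified genes (0.0009 and -0.13), ribosomal proteins (0.01 and -0.02) and leukocyte markers (0.12 and -0.13). Other scalings turned the sign of the median for ERK-response genes (0.02), the unfolded protein response (0.006), cornified genes (-0.0003) and ribosomal proteins (-0.04 and -0.01).

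**Figure D3:**
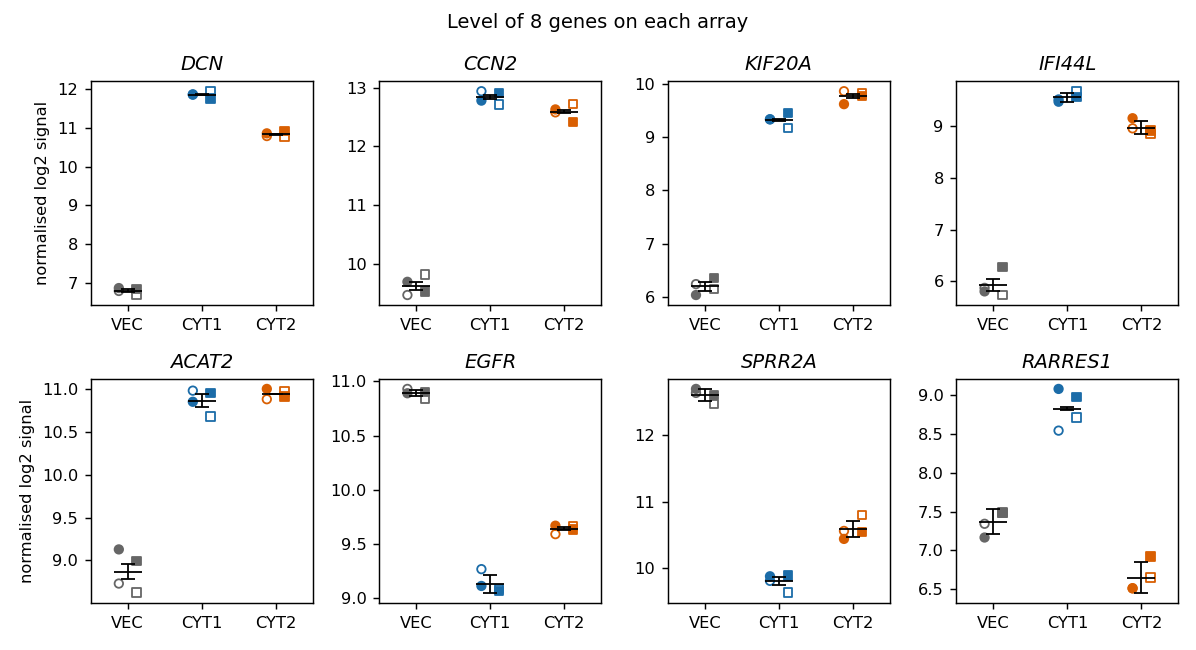
Normalised log2 levels of 8 genes on each of the 12 arrays by group, with circles and squares for biological numbers 1 and 2, filled and open symbols for technical numbers 1 and 2, and a bar with whiskers for the mean and SD of the 2 biological replicates. DCN lies 5.07 higher in CYT1 and 4.05 higher in CYT2 than in VEC, and EGFR 1.76 and 1.25 lower.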

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

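All tests of explanations given here were chosen only after the results were seen. Within each group, 1 array stood apart from the other 3 in the mean log2 level of a gene list in 7 of 99 Dixon tests, where 4.95 would be met by chance, about 1 in 20 groups; it did so in 0 of 6 such tests of the median signal and the number of detected probes. In CYT1, fatty acid genes lay at 9.478 on biological 1 technical 1 (others 9.519 to 9.522). ERBB receptors and ligands lay at 8.678 on the same array (others 8.556 to 8.573), and antigen presentation genes at 9.466 on biological 2 technical 2 (others 9.604 to 9.614). In VEC, hypoxia and glycolysis genes lay at 10.36 on biological 2 technical 1. In CYT2, NRF2 genes lay at 10.36 on biological 1 technical 2 (others 10.26 to 10.27). The unfolded protein response lay at 10.04 on biological 2 technical 2 (others 10.11), and luminal cancer line markers at 8.73 on biological 2 technical 1 (others 8.578 to 8.588).

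For 13 lists CYT2 and CYT1 differed by camera at its preset correlation. With an estimated correlation only mitosis stayed called (adjusted p = 0.0363), and the other 12 had adjusted p from 0.0869 to 0.184. The estimated correlations of these lists ran from -0.09015 for fibroblast markers to 0.03085 for matrix genes, against the preset 0.01. A simulated list of uncorrelated genes mostly lost its call too, so these losses do not show that correlated genes produced the calls. CYT2 minus CYT1, the medians were 0.5478 for mitosis, 0.3529 for G1/S, 0.2144 for NF-kB targets and cytokines, 0.2219 for luminal markers and 0.136 for epithelial adhesion. They were -0.4163 for fibroblast markers, -0.2917 for mesenchymal markers, -0.1424 for matrix genes, -0.1635 for YAP/TEAD targets and -0.1685 for TGF-beta targets. For hypoxia and glycolysis the median was -0.1422, for estrogen response -0.1489 and for p53 -0.1149. Of the genes called in opposite directions against VEC, RARRES1 differed by -2.181 and SLCO2A1 by 1.044.

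Mitosis genes were higher in both ICD groups than in VEC. A uniformly larger share of cycling cells might raise G1/S genes as much. The highest upper quartile of G1/S genes was 0.4886 in CYT2 (0.06844 in CYT1), below the lower quartile of mitosis genes of 1.898 (1.269 in CYT1). This cannot decide, as the lists started from different levels. On the VEC arrays the G1/S mean ran from 9.563 to 9.677, against 7.058 to 7.169 for mitosis genes. By camera the G1/S list was called up in CYT2 (adjusted p = 0.00189) and not in CYT1 (0.646). A larger share of cycling cells thus stays open. The deposited values, not normalised between arrays, argue against the normalisation as the whole cause. With them the list stayed called, with a lowest lower quartile of 0.7429. The lowest median over the other 3 scalings, 0.9943, fell just short of the limit of 1 set for its size. With background correction the median was 1.77 (quantile) and 1.856 (median scaling) in CYT1, and 2.231 and 2.319 in CYT2. Without it the median was 1.08 (quantile) and 0.9943 (deposited values) in CYT1, and 1.504 and 1.473 in CYT2. The size thus changed more with background correction than with scaling between arrays. A part played by the processing in the size stays open. A state of the VEC cells unrelated to the ICD could give the same pattern: arrays of the ICD groups differed by a mean SD of 0.2974, against 0.5517 and 0.5065 from VEC, as an effect common to both ICDs would also give. A change in late cell cycle genes caused by the ICDs thus stays an untested hypothesis.

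Fibroblast markers were higher in both ICD groups than in VEC, which admixed fibroblasts could cause. Fibroblasts of 1 kind as the whole cause would raise all these genes in CYT1 and CYT2 in 1 ratio, if the cells' own levels were equal in all groups. With the deposited signals the log2 ratio of the rises was 1.058 for DCN, 0.6266 for FAP, 0.3837 for COL6A3 and -0.04732 for S100A4. DCN lay above at least 2 others by 0.3874 or more at the replicates that bring them nearest, which argues against it for these genes under that condition. The other members had wide ranges over the 2 replicates per group. POSTN stood at 1.394 (0.1139 to 2.825), above DCN, COL1A1 at 0.8442 (0.1984 to 1.659) and TWIST1 at -0.2299 (up to 3.236). Fibroblasts as part of the cause, or of different kinds, stay open, as the collagen chain COL1A1 rose (1.51 in CYT1 and 1.01 in CYT2, named after its values were seen), and COL1A2, at -0.2413 in CYT1, lay near background. Of 15 fibroblast list genes on the array, 6, COL3A1 and LUM among them, were undetected on all 8 ICD arrays, and 5 were detected on every VEC array. A change of matrix and mesenchymal genes in the epithelial cells was not tested; 6 of the genes also belong to another list.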

How the results depend on the processing

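The alternatives that average arrays by technical number or use separate controls were chosen only after the result was seen. Signal over background and 2 replicates per group limit what each setting can call. With the biological number as a block, CYT1 against VEC gave 5719 probes, CYT2 against VEC 4732 and both 3894, but of the 3 lists called down for CYT2 only epithelial adhesion stayed called (15 lists in all). Between groups the biological numbers did not pair (r = -0.01314, -0.01301 and 0.008371 for differences between numbers 1 and 2). Averaging by technical number gave 5200, 4269 and 3481, and median scaling 6285, 5347 and 4393. Median scaling turned the larger share to higher, 3363 against 2922 for CYT1 and 2932 against 2415 for CYT2. With the deposited log2 values, not normalised between arrays, 2292 probes rose and 5037 fell for CYT1 (main 2895 and 3334). For CYT2 the counts were 2070 and 4560 (main 2558 and 2714). The median log2 fold change of all probes was then -0.08029 for CYT1 and -0.07602 for CYT2, against -0.044 and -0.04594 in the main fit. The excess of falls thus came with a shift of all probes, and its cause was not tested.

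CYT2 against CYT1, with 82 probes, depended on the setting, and the cause was not tested. Fewer were called with the biological block (2), no detection filter (2), each pair of groups alone (3), averaging by technical number (23), and that with a block (0 by limma, 2408 at unadjusted p under 0.05). More were called with quantile scaling of uncorrected signals (994, 545 up and 449 down), the deposited log2 values (706, 434 and 272), the strict filter (514, while lists fell from 13 to 10), duplicateCorrelation (1094), the technical number as a block (932), a trended robust prior (1096) and adjusted p under 0.10 (527, by construction).

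With technical arrays 1 alone 3720, 2972 and 1 probes were called for CYT1 and CYT2 against VEC and CYT2 against CYT1, and 2310 in both effects. With technical arrays 2 alone the counts were 3931, 2937, 2 and 2299. Requiring at least a 1.5-fold change left 3247 and 2580 against VEC and 2081 in both, of 4310, by construction.

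Leaving out 1 replicate leaves a group with 1 sample, assumed to vary like the other groups. It gave 3969 to 5688 probes for CYT1, 3020 to 4921 for CYT2, 2520 to 3406 for both, 2321 or 2318 with a separate VEC replicate for each ICD, and 0 to 3 for CYT2 against CYT1. By limma the 0 counts came without a CYT1 or CYT2 replicate, with 2474, 2484, 2270 and 2292 probes at unadjusted p under 0.05. Fewer samples explain lower counts by construction.

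Of the 14, 17 and 13 lists called, an estimated correlation kept 0 by limma, 1 and 1, in each case the mitosis genes. The fry test in one direction called 26, 27 and 19, and in either direction 32, 32 and 30, as it does not compare with other genes. Leaving out replicates gave 14 to 15, 16 to 18 and 10 to 13.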

Other observations

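The gene families described here, grouped by the start of their symbols, were chosen only after the result was seen. Of 170 families tested, none stayed called with an estimated correlation (adjusted p = 0.734 or more for CYT1, 0.787 for CYT2 and 0.997 between them). Mitochondrial ribosomal proteins of the large subunit were lower with either ICD. With CYT1, 25 of 49 MRPL genes fell and 0 rose by limma (median -0.29, adjusted p = 0.000863), and 10 of 29 MRPS genes of the small subunit fell (median -0.23, adjusted p = 0.0475). With CYT2, 13 of 49 MRPL genes fell (median -0.24, adjusted p = 0.00907), while the MRPS genes, with 7 falls and 1 rise, were not called (adjusted p = 0.224). Nucleoporins (8 of 20 fell, median -0.34, adjusted p = 0.00435), chaperonin CCT subunits (6 of 9, median -0.44) and ALG genes of N-glycan assembly (6 of 12, median -0.35) were lower with CYT1. For CYT2 they had 10, 6 and 6 falls but were not called (medians -0.27, -0.35 and -0.33, adjusted p = 0.0599, 0.056 and 0.067). Integrator subunits (7 of 15, median -0.33, adjusted p = 0.0241) were lower with CYT2, and not called for CYT1 (6 falls, adjusted p = 0.0845).

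Probes annotated to small nucleolar RNA genes read higher with the ICDs, and which transcripts they measure was not tested. Of 40 SNORD genes 12 rose and 2 fell with CYT1 (median 0.26, adjusted p = 0.0475) and 13 rose with CYT2 (median 0.28, adjusted p = 0.00246). Of 28 SNORA genes 12 and 13 rose (medians 0.32 and 0.38). Kinesins rose in 10 of 19 cases with CYT1 (median 0.53, adjusted p = 0.025) and 11 with CYT2 (median 1.04, adjusted p = 0.000787), and were higher in CYT2 than in CYT1 as a family (median 0.39, adjusted p = 0.000251), as were 9 MCM genes (median 0.28, adjusted p = 0.00761), with 0 members called by limma. Collagens had 10 rises and 2 falls among 19 with either ICD (medians 0.47 and 0.59), and 7 of 9 IFI genes rose with CYT2 (median 0.46), while for CYT1, with 6 rises and 2 falls, they were not called (adjusted p = 0.066).

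Arrays that share a technical number resemble each other more than arrays titled technical replicates of the same biological number. The mean SD of log2 differences was 0.224 against 0.239 in VEC, 0.241 against 0.274 in CYT1 and 0.231 against 0.252 in CYT2, over 12254 probes. A run effect shared by all groups could cause this, but single technical differences correlated less between groups (mean 0.05121, from 0.02905 to 0.08132) than within them (0.1636, from 0.1121 to 0.2297), a ratio of 0.313, which argues against it as the whole cause, while averaged ones correlated between all groups (r = 0.08022, 0.08694 and 0.09771), as a shared part would give. Biological and technical numbers exchanged in the titles would leave no shared biological difference, and its highest correlation was 0.006298, in line with an exchange. The letter A or B in the signal column names went with technical number 1 or 2. The titles were kept as given, and whether the numbers were exchanged stays open. If they were, each averaged replicate would mix both biological samples of its group, and the SEs and p-values would measure technical spread.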
